A study of Mus musculus with 12 samples.

How the data were processed

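Gene expression was measured on 12 Affymetrix arrays of hearts dissected from mouse embryos at embryonic day 8.75. There were 4 groups of 3 arrays each, taken from the sample titles: wild type (WT), Nkx2-5 KO, Tbx5 KO and a double KO that lacks both genes. The titles number the arrays of a group as biological replicates. Per the labels, total RNA was isolated with a PicoPure kit, amplified with a NuGEN Ovation kit and labelled with biotin by a NuGEN Encore module. The software that summarized and normalized the arrays is not given in the sources used here.

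The deposited values are log2 expression values per probe set, as the authors made them. The scale was checked on the values, which ran from 3.21 to 14.7 over all arrays, with array medians from 8.05 to 8.25. The table held 35557 probe sets, and each of its columns belonged to 1 of the 12 arrays. No further normalization was applied. Pearson correlations across probe sets, which are not independent replicates, lay between 0.969 and 0.984 for arrays of a group and between 0.958 and 0.981 for arrays of different groups. No pair of arrays held identical values (0 pairs). For arrays, the number per group limits the precision.

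Probe sets were named with the platform's annotation. Of them, 21789 carried exactly 1 gene symbol, 1621 carried several and 12147 had none listed. Of those with exactly 1 symbol, 21698 matched the mouse RefSeq gene table of assembly GRCm38.p6 by Entrez number, and 0 symbols were updated from it. The table was used for names, for membership of the X and Y chromosomes and for the order of neighbouring genes. Where a gene had several probe sets (999 genes), the one with the highest mean over all 12 arrays was kept. This gave 19938 genes, all of which were tested, with no filter on dim signals.

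A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual degrees of freedom and 4.51 prior degrees of freedom. Tests were two-sided. A gene was called when its p, adjusted by Benjamini and Hochberg over the 19938 genes within a comparison, was under 0.05. The 7 comparisons were each KO with WT, the 3 pairs of KO groups, and the non-additive term, which is the double KO change minus the sum of both single KO changes on the log2 scale. A gene counted as changed beyond both single KOs when the double KO differed in the same direction from WT, Nkx2-5 KO and Tbx5 KO. Overlaps of calls were set beside the product of the call rates and beside 100 simulations of unchanged groups compared with the same WT arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

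Before the data were examined, 29 gene lists were fixed, with 538 entries, of which 508 were measured. They were targeted genes, cardiac transcription factors, sarcomere and myofibril, calcium handling, ion channels and conduction, chamber and trabecular myocardium, second heart field and progenitor, atrioventricular canal and inflow tract, endocardium and endothelium, erythroid cells, platelet, macrophage and other blood cells, foregut and visceral endoderm, pharyngeal mesenchyme and neural crest, proepicardium and epicardium, neural tissue, anterior Hox genes, extracellular matrix and cushion, smooth muscle, BMP response, FGF response, Wnt response, Notch response, cell cycle, p53 and apoptosis, hypoxia and glycolysis, oxidative metabolism, unfolded protein and heat shock response, sex-linked genes, and widely used reference genes. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. Members were counted at the adjusted p over all genes and also when adjusted over the list alone. Lists of maternally expressed imprinted genes, paternally expressed imprinted genes, trophoblast and decidua, immediate early genes and replication-dependent histones were added after the data had been seen. They were tested with camera and against 10000 random lists matched on expression, as a family of 20 tests.

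The rule for named genes was also set before the data were examined. It takes Nkx2-5 and Tbx5, 10 cardiac genes (Gata4, Nppa, Myh6, Myl2, Gja5, Hcn4, Isl1, Bmp10, Tbx20 and Hand1), the 8 largest rises and 8 largest falls among called genes whose values did not overlap between the groups compared, and up to 4 called members of each list with the largest change. Predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors were left out of the largest changes, and the non-additive term had no overlap condition. For pairs of KO groups the rule takes 4 rises and 4 falls. Other genes are named only where a list, a count or a pattern calls for them, and were then chosen after their values were seen.

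The alternatives tried were quantile normalization of the log2 values again, each array centred on its median, 1 in 3 probe sets, the dimmest, left out, the mean of all probe sets of a gene, eBayes with an intensity trend, robust eBayes, array weights, a fit to only the arrays of the groups compared, a replicate block, an adjusted p under 0.01, an absolute log2 change of at least 1, and each replicate left out in turn. After the data had been seen, counts were also made without X- and Y-linked genes and without the imprinted, trophoblast and decidua genes. Each comparison was repeated on other splits of the same arrays. The fit was tested on simulated data with 50 changed genes per effect size: with 3 arrays per group it recovered 32% of the genes changed by 0.5 log2 units, 96% at 1 unit and 98% at 1.5 units. For the non-additive term it recovered 8%, 80% and 92%. False calls numbered 0 to 9 per comparison. The simulated errors were independent between genes and equally spread over the arrays. Real genes varied together and real arrays differed in weight, so these rates may be too favourable for the real data. Probe sets with several or no gene symbols were left out of the comparisons, since they could not be assigned to a gene, and were tested only by themselves.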

Results

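The data were 12 arrays of dissected hearts from early mouse embryos, at a stage when the heart is a looping tube that has begun to form chambers. WT, Nkx2-5 KO, Tbx5 KO and double KO hearts were each measured on 3 arrays, which the titles number as biological replicates. Nkx2-5 and Tbx5 are cardiac transcription factors, and the crossing of their losses asks what each controls alone and what depends on both. Array medians were 8.05 to 8.25 log2 units. The standard deviation over probe sets was 2.17, 2.19 and 2.18 on the WT arrays and 2.09, 2.05 and 2.10 on the double KO arrays. All changes below are log2 differences between group means, followed by ± their standard error (SE) from the limma fit with n = 3 arrays in each group. Levels are means ± SD over 3 arrays.

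The targeted genes came first. The Nkx2-5 probe set (10449292) gave 9.35 ± 0.01 in WT, 8.94 ± 0.21 in Nkx2-5 KO, 9.35 ± 0.04 in Tbx5 KO and 9.08 ± 0.12 in double KO hearts. It changed by -0.41 ± 0.11 in Nkx2-5 KO (adjusted p = 0.0499), by 0.00 ± 0.11 in Tbx5 KO and by -0.27 ± 0.11 in double KO (adjusted p = 0.0878, and 0.0104 with centred arrays). The call in Nkx2-5 KO ended without WT replicate 1, 2 or 3 or Nkx2-5 KO replicate 1 or 2 (adjusted p 0.0948 to 0.138), after quantile normalization again (0.0543), with an intensity trend (0.0635), with only the arrays compared (0.1) and with a replicate block (0.0886). The Tbx5 probe set (10525030) gave 10.06 ± 0.14 in WT, 10.32 ± 0.19 in Nkx2-5 KO, 10.53 ± 0.17 in Tbx5 KO and 10.60 ± 0.26 in double KO hearts. It was 0.47 ± 0.15 in Tbx5 KO (adjusted p = 0.127, and 0.0425 with array weights) and rose by 0.54 ± 0.15 in double KO (adjusted p = 0.0193), a call that ended without WT replicate 3, double KO replicate 2 or double KO replicate 3 (adjusted p 0.0662 to 0.0742) and with each array centred on its median (0.073). The labels do not say which part of either gene was removed. A probe set outside the removed part measures RNA that a mutant can still make, so these values do not check the genotypes, and the groups are as labelled.

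In Nkx2-5 KO hearts, 7 of 20 genes of chamber muscle fell, and single genes of the inflow region and of heart progenitors rose. Nppa, the gene of atrial natriuretic peptide and a marker of chamber muscle, fell by 2.65 ± 0.26 from a WT level of 13.37 ± 0.13 (6.26-fold, adjusted p = 0.00026). Its relative Nppb fell by 2.79 ± 0.26 (adjusted p = 0.00023), and Smpx, a small muscle protein encoded on the X chromosome, fell too (-2.77 ± 0.24). Pln, whose product phospholamban restrains the calcium pump of the sarcoplasmic reticulum, was lower (-2.22 ± 0.27, adjusted p = 0.00119). Vsnl1, which encodes a calcium sensor, rose by 1.80 ± 0.19 (adjusted p = 0.000402), and Fgf10, a growth factor made by second heart field progenitors, by 1.85 ± 0.26 (adjusted p = 0.00283). Bmp10, a growth factor of the trabecular layer, was 0.29 ± 0.21 (adjusted p = 0.571), Myh6, the alpha myosin heavy chain, 0.05 ± 0.14, Gata4 0.21 ± 0.13 and Tbx20 0.20 ± 0.14, none of them called.

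Of the 20 measured genes of chamber and trabecular myocardium, 7 fell and 0 rose, and adjusted over the list alone 9 fell and 2 rose. The list lay below other genes (median -0.388, camera adjusted p = 1.2e-05), with adjusted p = 0.0949 with an estimated correlation. Besides Nppa, Nppb and Smpx, the members that fell included Hopx, a homeodomain protein of cardiac muscle (-0.71 ± 0.11). Gja5, which encodes the gap junction protein connexin 40, fell by 1.76 ± 0.36 (adjusted p = 0.0191), a call that ended without WT replicate 1 (0.0774), WT replicate 3 (0.0511) or Nkx2-5 KO replicate 1 (0.0887). Among 39 genes of sarcomere and myofibril, 5 fell and 0 rose (8 and 0 adjusted over the list alone). Among them were Mylk3, a kinase of cardiac myosin light chain (-0.78 ± 0.10), and Xirp1, an actin-binding protein of intercalated discs (-0.65 ± 0.08). That list had a camera adjusted p = 0.00078, which was 0.0549 with array weights, and adjusted p = 0.475 with an estimated correlation. Pln and Casq2, the calcium store protein of the sarcoplasmic reticulum (-1.31 ± 0.16), were the 2 of 18 calcium handling genes that fell, with 0 rising (2 and 1 adjusted over the list alone, list adjusted p = 0.0866). With the list higher, that was 0.00942 after quantile normalization again, 0.0172 with array weights, 0.0474 without WT replicate 2 and 0.0493 without Nkx2-5 KO replicate 2. Of 21 genes of ion channels and conduction, 2 rose and 3 fell, the same numbers adjusted over the list alone (list adjusted p = 0.656). Kcna5, a potassium channel of atrial muscle, fell by 1.73 ± 0.19, whereas Cacna2d2, a calcium channel subunit, rose by 0.96 ± 0.15. Cardiac transcription factors numbered 2 higher and 4 lower of 22 (3 and 5 adjusted over the list alone, list adjusted p = 0.995, with a median of 0.0834 and a mean of -0.016). Hand1, a transcription factor of the outer curvature, was -0.52 ± 0.13 (adjusted p = 0.0424), a call that ended without WT replicate 1 or 3 or any Nkx2-5 KO array (0.0875 to 0.156) and with only the arrays compared (0.0804). Myl2, the ventricular myosin light chain, was -0.41 ± 0.09 (adjusted p = 0.0234), which ended without any 1 of the WT arrays or Nkx2-5 KO replicate 1 or 3 (0.0577 to 0.0936).

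The 15 genes of the atrioventricular canal and inflow tract split, with 4 higher and 3 lower (6 and 5 adjusted over the list alone, list adjusted p = 0.685). Hcn4, the pacemaker channel, rose by 0.90 ± 0.18 (adjusted p = 0.0176), a call that ended without WT replicate 1 (0.0774), Nkx2-5 KO replicate 1 (0.0645) or Nkx2-5 KO replicate 3 (0.0701). Isl1, a transcription factor of the second heart field and the sinus node, rose by 1.48 ± 0.30 (adjusted p = 0.0192), which ended without WT replicate 3 (0.0687), Nkx2-5 KO replicate 1 (0.0652) or Nkx2-5 KO replicate 2 (0.0548). In the list second heart field and progenitor, 2 of 24 rose and 1 fell (5 and 1 adjusted over the list alone). Its camera adjusted p = 0.0324 became 0.155 without WT replicate 1, 0.0823 without Nkx2-5 KO replicate 2, 0.0726 with array weights and adjusted p = 0.331 with an estimated correlation. FGF response genes stood at 2 higher and 0 lower of 8 (3 and 0 adjusted over the list alone, camera adjusted p = 0.000813, adjusted p = 0.272 with an estimated correlation).

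Some genes of glycolysis and of the response to low oxygen rose. Of 22 genes of hypoxia and glycolysis, 8 rose and 0 fell, and 16 rose adjusted over the list alone. The list median was 0.66 (camera adjusted p = 3.7e-13, adjusted p = 0.229 with an estimated correlation), with Vegfa, the vascular growth factor, at 1.04 ± 0.16 (adjusted p = 0.00567). The unfolded protein and heat shock response list had 6 higher and 1 lower of 15 (8 and 1 adjusted over the list alone, camera adjusted p = 0.000144, adjusted p = 0.229 with an estimated correlation). In it the stress transcription factors Atf3 (1.45 ± 0.19) and Ddit3 (1.31 ± 0.22) rose and the chaperone gene Hsph1 (-0.95 ± 0.12) fell. Oxidative metabolism had 2 lower and 0 higher of 27 (5 and 1 adjusted over the list alone, median -0.176, camera adjusted p = 0.000256, adjusted p = 0.306 with an estimated correlation). Idh3a, a subunit of an enzyme of the citric acid cycle, was lower (-0.79 ± 0.11). The cell cycle list lay lower with a median of -0.254 (camera adjusted p = 2.84e-05, adjusted p = 0.522 with an estimated correlation, 0.233 by fry), although only 1 of its 28 genes fell, and 1 adjusted over the list alone. In p53 and apoptosis, 2 of 16 rose, Btg2 (1.08 ± 0.17) and Sesn2 (0.87 ± 0.14), and 0 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.173).

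Few markers of other cell types were called in Nkx2-5 KO. In foregut and visceral endoderm 1 of 27 rose and 0 fell, the same numbers adjusted over the list alone, with a list median of 0.178 (camera adjusted p = 0.000185, adjusted p = 0.229 with an estimated correlation). The endocardium and endothelium list had 1 of 28 higher and 0 lower (2 and 0 adjusted over the list alone). Its camera adjusted p = 0.0324 was 0.75 without WT replicate 1, 0.0824 without Nkx2-5 KO replicate 1, 0.0612 with only the arrays compared, 0.339 by fry and adjusted p = 0.583 with an estimated correlation. Neural tissue had 1 higher, Pax6 (1.70 ± 0.16), an eye and neural transcription factor, and 1 lower of 19 (3 and 1 adjusted over the list alone, list adjusted p = 0.243). Proepicardium and epicardium had 1 higher, the retinoic acid enzyme gene Aldh1a1 (1.02 ± 0.16), and 1 lower of 14 (1 and 2 adjusted over the list alone, list adjusted p = 0.0616). The list adjusted p was 0.000168 without WT replicate 1 and 0.0252 without WT replicate 3, with the list lower. Extracellular matrix and cushion had 1 and 1 of 29 (3 and 2 adjusted over the list alone, list adjusted p = 0.19), and 0.0414 without WT replicate 2, with the list higher. Platelet, macrophage and other blood cells had 0 higher and 1 lower of 18 (list adjusted p = 0.552). No member was called among erythroid cells (0 of 13, list adjusted p = 0.227, and 1.17e-05 without WT replicate 2, with the list lower), pharyngeal mesenchyme and neural crest (0 of 19, with 1 higher adjusted over the list alone, 0.495), anterior Hox genes (0 of 14, 0.363, and 0.0205 without WT replicate 1), smooth muscle (0 of 12, 0.287), BMP response (0 of 11, with 1 higher adjusted over the list alone, 0.416), Wnt response (0 of 8, 0.926), Notch response (0 of 6, 0.568) or widely used reference genes (0 of 9, 0.13, and 0.0395 by fry).

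Sex-linked genes moved in the same comparison. The Y-linked genes Eif2s3y and Uty rose by 4.79 ± 0.36 and 3.65 ± 0.28, and Xist, the RNA that silences an X chromosome, fell by 4.92 ± 0.35. In the list of sex-linked genes 2 of 4 rose and 1 fell (3 and 1 adjusted over the list alone), with a camera adjusted p = 0.0199 that was 0.0578 without Nkx2-5 KO replicate 2, 0.0543 with array weights, 0.107 with only the arrays compared and adjusted p = 0.229 with an estimated correlation. Xist lay between 11.5 and 12.3 in the 6 WT and Tbx5 KO arrays and between 6.44 and 8.16 in the 6 Nkx2-5 KO and double KO arrays. The mean of Eif2s3y and Uty lay between 5.23 and 6.79 in the former and between 9.88 and 10.3 in the latter. Plagl1, an imprinted gene, fell by 3.37 ± 0.51 (adjusted p = 0.00565). Other large changes, among those whose calls held without any 1 array, were rises of Prm1, a protamine gene (from 8.62 ± 0.44 to 11.12 ± 0.45), Sparcl1, a matrix protein (2.06 ± 0.18), and the X-linked Ap1s2 (1.97 ± 0.18), and a fall of Plac8 (-2.52 ± 0.26).

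In all, 884 of 19938 genes (4.43%) differed between Nkx2-5 KO and WT, 367 higher and 517 lower, and 142 of them by at least 1 log2 unit. With each array centred on its median, 209 were higher and 646 lower. The balance turned without WT replicate 2 (466 higher, 437 lower), without Nkx2-5 KO replicate 3 (190 and 156) and among the 142 genes (78 and 64). The total was 240 without WT replicate 1, 335 without WT replicate 3, 169 without Nkx2-5 KO replicate 1, 346 without Nkx2-5 KO replicate 3 and 2132 with array weights.

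**Figure D1:**
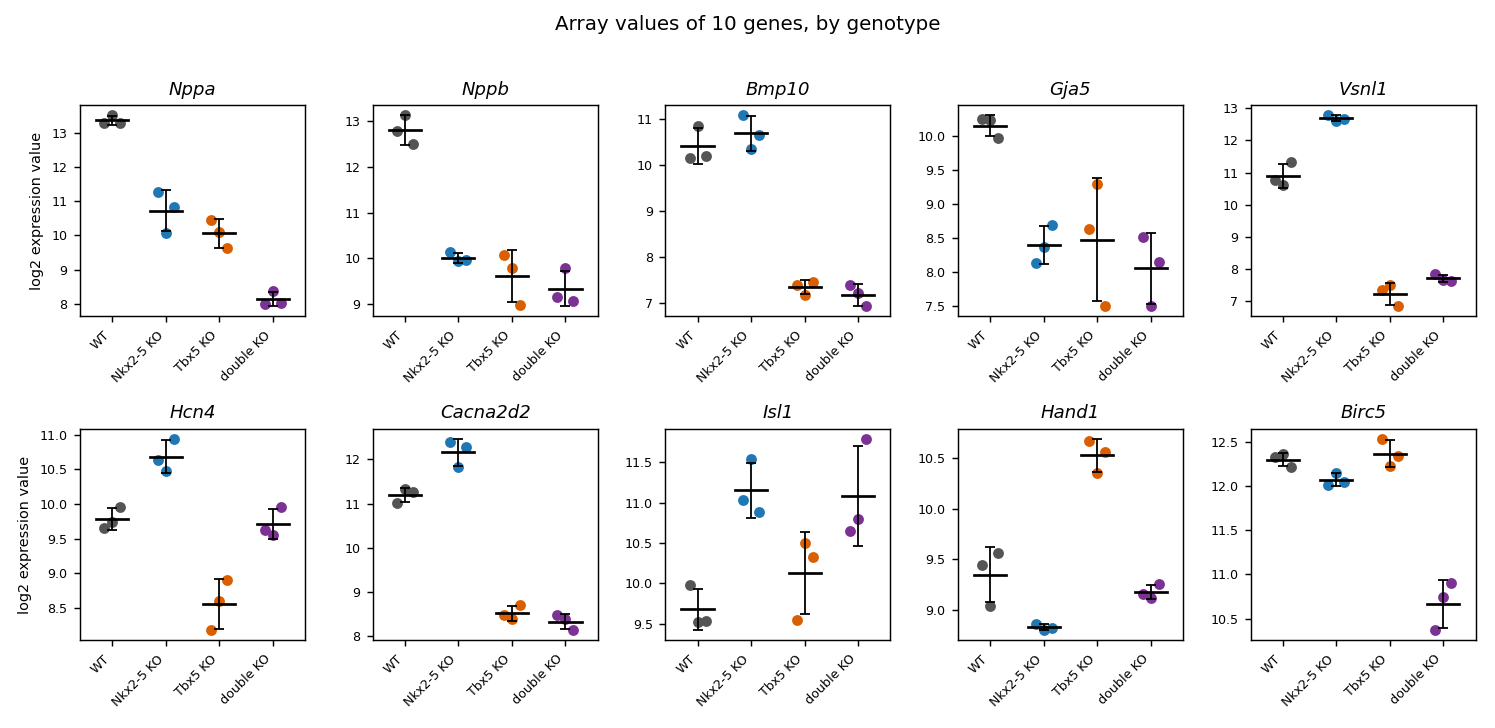
The y axis of each panel is the log2 expression value of 1 of 10 genes, and the x axis gives the 4 groups, with points for single arrays, a line for the mean and bars for the SD (n = 3). Mean Nppa fell from 13.37 in WT to 8.13 in double KO, and mean Vsnl1 was 12.70 in Nkx2-5 KO and 7.22 in Tbx5 KO.

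In Tbx5 KO hearts, genes of chamber muscle and of the inflow tract fell, as did 7 of 21 genes of ion channels and conduction. Vsnl1 fell by 3.67 ± 0.19 from 10.90 ± 0.37 in WT (12.8-fold, adjusted p = 1.49e-06). Nppa (-3.31 ± 0.26, adjusted p = 3.74e-05), Nppb (-3.19 ± 0.26) and Bmp10 (-3.07 ± 0.21, adjusted p = 1.79e-05) fell as well. Hand1 rose by 1.19 ± 0.13 (adjusted p = 0.000462), and the signalling ligand gene Wnt5a by 1.44 ± 0.13. Genes of placenta and decidua rose as well, led by the placental hormone gene Prl3d3 (4.32 ± 0.35, adjusted p = 4.71e-05) and by Erv3 (3.54 ± 0.19). The arrays do not tell which cells a raised RNA came from, heart or carried-over tissue, and this holds for Hand1 too. Isl1 (0.45 ± 0.30), Myh6 (-0.11 ± 0.14), Myl2 (-0.25 ± 0.09, adjusted p = 0.191, and 0.0454 with an intensity trend), Gata4 (0.12 ± 0.13) and Tbx20 (0.36 ± 0.14) were not called.

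Chamber and trabecular myocardium had 10 of 20 genes lower and 0 higher (11 and 0 adjusted over the list alone). Its median was -0.55, and its camera adjusted p = 1.49e-12 held with an estimated correlation (adjusted p = 0.00661). Gja5 was -1.68 ± 0.36 (adjusted p = 0.0316), and this call ended without WT replicate 1, 2 or 3, Tbx5 KO replicate 1 or Tbx5 KO replicate 3 (0.0682 to 0.099), with only the arrays compared (0.0727) and with a replicate block (0.053). The atrioventricular canal and inflow tract list had 8 of 15 lower and 0 higher (9 and 3 adjusted over the list alone). Its median was -0.964, and its call held with an estimated correlation (camera adjusted p = 1.68e-06, adjusted p = 0.0304 with an estimated correlation). Members that fell included Hcn4 (-1.22 ± 0.18, adjusted p = 0.00416) and the orphan nuclear receptor genes Nr2f2 (-1.84 ± 0.23) and Nr2f1 (-1.39 ± 0.16), which act in atrial and venous tissue. Ion channels and conduction had 7 of 21 lower and 0 higher, the same numbers adjusted over the list alone (median -0.142, camera adjusted p = 2.54e-05, adjusted p = 0.0778 with an estimated correlation). Cacna2d2 (-2.69 ± 0.15) and Kcna5 (-2.44 ± 0.19) were among them. Calcium handling split, with 2 higher and 4 lower of 18 (5 and 4 adjusted over the list alone, list adjusted p = 0.994), Pln (-2.21 ± 0.27) and Casq2 (-1.07 ± 0.16) being lower. In sarcomere and myofibril 1 of 39 rose and 3 fell (2 and 4 adjusted over the list alone, list adjusted p = 0.705), including Myoz2, a Z-disc protein (-1.76 ± 0.31).

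Cardiac transcription factors as a list lay higher in Tbx5 KO, with 3 higher and 1 lower of 22 (6 and 1 adjusted over the list alone, median 0.285, camera adjusted p = 8.88e-06, adjusted p = 0.0304 with an estimated correlation). Hand1 and Myocd, a coactivator of muscle genes (0.60 ± 0.10), rose, and Hopx (-1.30 ± 0.11) fell. The source cells of the Hand1 RNA are not known. Second heart field and progenitor had 2 higher and 1 lower of 24 (3 and 1 adjusted over the list alone, list adjusted p = 0.75). In Wnt response, 1 of 8 rose, the transcription factor gene Lef1 (1.40 ± 0.13), and 0 fell, the same numbers adjusted over the list alone (list adjusted p = 0.208). Proepicardium and epicardium had 3 of 14 lower and 0 higher (8 and 1 adjusted over the list alone). The list median was -0.511 (camera adjusted p = 7e-06, adjusted p = 0.333 with an estimated correlation, 0.0687 by fry). Oxidative metabolism had 3 of 27 lower and 0 higher (5 and 0 adjusted over the list alone), among them the fatty acid carrier gene Cd36 (-1.72 ± 0.25) and Idh3a (-0.71 ± 0.11). Its camera adjusted p = 0.0016 became 0.102 without Tbx5 KO replicate 2, 0.0644 after quantile normalization again, 0.0732 by fry and adjusted p = 0.463 with an estimated correlation. Hypoxia and glycolysis had 0 of 22 higher and 0 lower, also adjusted over the list alone, although the list median of 0.302 lay above other genes (camera adjusted p = 4.67e-08, adjusted p = 0.463 with an estimated correlation, 0.0896 by fry).

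Among markers of other cells in Tbx5 KO, erythroid cells had 0 of 13 called and a median of -0.624. The list's camera adjusted p = 0.0016 became 0.274 without WT replicate 1, 0.451 by fry and adjusted p = 0.704 with an estimated correlation. Endocardium and endothelium had 1 higher, Sox17, an endothelial transcription factor (0.66 ± 0.10), and 1 lower of 28 (list adjusted p = 0.594, and 0.00306 without WT replicate 1, with the list lower). Neural tissue had 1 higher, Pax6 (0.97 ± 0.16), and 1 lower, the neuronal tubulin gene Tubb3 (-1.73 ± 0.27), of 19 (list adjusted p = 0.606). Extracellular matrix and cushion had 1 higher and 1 lower of 29 (4 and 4 adjusted over the list alone, 0.705), pharyngeal mesenchyme and neural crest 1 higher of 19 (0.75), platelet, macrophage and other blood cells 1 lower of 18 (2 adjusted over the list alone, 0.405), and cell cycle 1 higher and 1 lower of 28 (0.092, and 0.0112 with only the arrays compared, with the list lower). The lists foregut and visceral endoderm (0 of 27, list adjusted p = 0.335, and 0.0374 without WT replicate 3), anterior Hox genes (0 of 14, 0.335, and 0.0171 without WT replicate 1), smooth muscle (0 of 12, 0.29), BMP response (0 of 11, 0.705), FGF response (0 of 8, 0.342), Notch response (0 of 6, 0.335), p53 and apoptosis (0 of 16, 0.606), unfolded protein and heat shock response (0 of 15, 0.994), sex-linked genes (0 of 4, 0.692) and widely used reference genes (0 of 9, 0.436) had no called member. Adjusted over the list alone, smooth muscle had 0 higher and 1 lower, BMP response 1 and 1, FGF response 3 and 1, p53 and apoptosis 2 and 0, and the unfolded protein list 2 and 2. Of the 29 measured genes of the trophoblast and decidua list, made after such genes had been seen to be high here, 13 rose and 0 fell (median 0.325, camera adjusted p = 2.02e-19, adjusted p = 0.000294 with an estimated correlation). They included Prl8a2 (3.15 ± 0.27), Prl2c5 (2.73 ± 0.31), the protease inhibitor gene A2m (2.14 ± 0.25) and the granzyme gene Gzmd (2.02 ± 0.29).

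Altogether 461 genes (2.31%) differed between Tbx5 KO and WT, 199 higher and 262 lower, with 117 at or beyond 1 log2 unit. Centred arrays gave 131 higher and 294 lower, and without Tbx5 KO replicate 2 the balance turned (154 and 140). The total was 256 without WT replicate 1, 212 without WT replicate 3, 216, 294 and 246 without Tbx5 KO replicates 1, 2 and 3, and 933 with array weights.

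**Figure D2:**
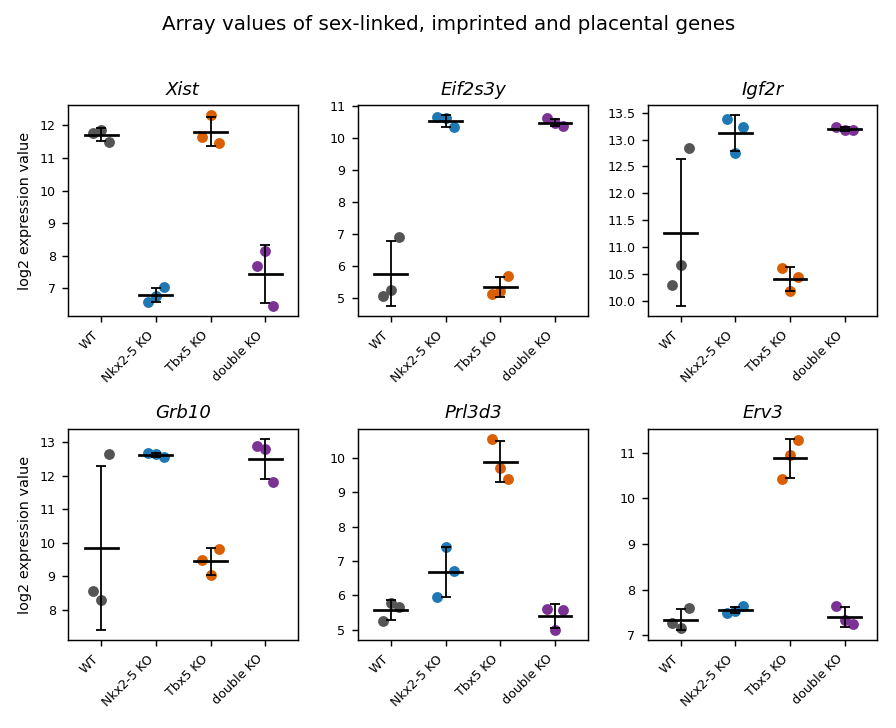
The y axis of each panel is the log2 expression value of a sex-linked gene (Xist, Eif2s3y), an imprinted gene (Igf2r, Grb10) or a gene of placental tissue (Prl3d3, Erv3), and the x axis gives the 4 groups, with points for single arrays, a line for the mean and bars for the SD (n = 3). Mean Prl3d3 was 9.89 in Tbx5 KO and 5.57 in WT, and the 3 WT values of Grb10 spanned 4.36 log2 units.

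In double KO hearts, 14 of 20 chamber genes and 26 of 28 genes of the cell cycle fell. Nppa fell by 5.24 ± 0.26 (37.7-fold, adjusted p = 4.14e-07), to 8.13 ± 0.20. Angpt1, a ligand made by heart muscle that acts on endothelial cells, fell by 4.17 ± 0.19 (adjusted p = 3.34e-07). Nppb (-3.46 ± 0.26), Bmp10 (-3.23 ± 0.21) and Vsnl1 (-3.19 ± 0.19) were lower too. Birc5, which encodes the mitotic protein survivin, fell by 1.63 ± 0.13 (adjusted p = 1e-05), and Rrm2, a subunit of the enzyme that makes DNA precursors, was lower (-2.14 ± 0.25). Esm1, an endothelial proteoglycan, rose by 2.79 ± 0.32 (adjusted p = 9e-05), and Isl1 by 1.41 ± 0.30 (adjusted p = 0.00524). Hcn4 (-0.07 ± 0.18), Hand1 (-0.17 ± 0.13), Gata4 (0.24 ± 0.13) and Tbx20 (0.06 ± 0.14) were not called.

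Chamber and trabecular myocardium had 14 of 20 genes lower and 1 higher (15 and 1 adjusted over the list alone). The median was -0.855, with a camera adjusted p = 2.16e-09 that held with an estimated correlation (adjusted p = 0.0193). Gja5 (-2.10 ± 0.36) and Irx4, a ventricular transcription factor (-0.89 ± 0.17), fell. Sarcomere and myofibril moved both ways, with 6 higher and 11 lower of 39, the same numbers adjusted over the list alone. The list test gave adjusted p = 0.0845, and 0.0339 with each array centred on its median, 0.0207 without WT replicate 3 and 0.0172 by fry, with the list lower in each. Myh6 (-0.81 ± 0.14, adjusted p = 0.00121), Myl2 (from 13.99 ± 0.05 to 12.99 ± 0.12, adjusted p = 2.17e-05), Smpx (-3.25 ± 0.24) and the thin filament gene Lmod2 (-1.09 ± 0.18) were lower. Ion channels and conduction had 8 lower and 1 higher of 21, the same numbers adjusted over the list alone. That list had a median of 0.00497, a mean of -0.483 and a camera adjusted p = 0.0308 towards lower values, which was 0.073 after quantile normalization again, 0.0733 without WT replicate 2 and adjusted p = 0.435 with an estimated correlation. Cacna2d2 (-2.88 ± 0.15), Kcna5 (-1.96 ± 0.19) and Popdc3, a membrane protein that binds cyclic AMP (-1.19 ± 0.09), fell. Calcium handling had 3 higher and 4 lower of 18, the same adjusted over the list alone (list adjusted p = 0.834, median 0.151, mean -0.0714), with Pln at -2.96 ± 0.27 and the calcium channel gene Cacna1c at 1.18 ± 0.13.

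Cardiac transcription factors had 6 higher and 5 lower of 22 (9 and 5 adjusted over the list alone, list adjusted p = 0.551, and 0.0131 after quantile normalization again, with the list higher), Gata6 (0.68 ± 0.11) rising and Hopx (-1.61 ± 0.11) falling. Second heart field and progenitor had 5 higher and 2 lower of 24 (5 and 4 adjusted over the list alone, 0.47), with rises of the transcription factor genes Prdm1 (1.50 ± 0.32) and Foxf1 (1.48 ± 0.35) and a fall of the guidance ligand gene Sema3c (-1.63 ± 0.26). In the atrioventricular canal and inflow tract, 6 of 15 fell and 1 rose (6 and 2 adjusted over the list alone, median -0.233), among them Rspo3, a Wnt enhancer (-1.39 ± 0.23). That list's camera adjusted p = 0.0137 became 0.0791 without the dimmest probe sets and adjusted p = 0.275 with an estimated correlation.

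The cell cycle list stood out in double KO, with 26 of 28 genes lower and 0 higher, the same numbers adjusted over the list alone. Its median was -1.07 (camera adjusted p = 5.33e-18, adjusted p = 0.275 with an estimated correlation, 0.000384 by fry). Ccne2, a cyclin of S phase entry (-1.61 ± 0.20), and Cdk1, the mitotic kinase (-1.51 ± 0.23), were among those that fell. Hypoxia and glycolysis had 13 of 22 higher and 0 lower (16 and 0 adjusted over the list alone, median 0.656, camera adjusted p = 2.29e-06, adjusted p = 0.45 with an estimated correlation). Members that rose included Egln3, an oxygen-sensing hydroxylase (1.99 ± 0.45), Ndrg1 (1.44 ± 0.23) and Ankrd37 (1.34 ± 0.28). Oxidative metabolism had 12 of 27 lower and 1 higher (15 and 1 adjusted over the list alone, median -0.321, camera adjusted p = 7e-06, adjusted p = 0.275 with an estimated correlation). It was led by lipoprotein lipase, Lpl (-1.89 ± 0.13), Idh3a (-1.55 ± 0.11) and the cytochrome oxidase subunit gene Cox6a2 (-1.17 ± 0.29). The unfolded protein and heat shock response had 7 higher and 3 lower of 15 (8 and 4 adjusted over the list alone, list adjusted p = 0.388, and 0.0142 after quantile normalization again, with the list higher). Atf3 (1.89 ± 0.19) rose and Hsph1 (-1.64 ± 0.12) fell. In p53 and apoptosis 4 of 16 rose, Btg2 (1.65 ± 0.17) being the largest, and 3 fell (6 and 5 adjusted over the list alone, 0.551). FGF response had 2 of 8 higher, Il17rd (1.54 ± 0.21) and Etv5 (1.36 ± 0.22), and 0 lower, the same adjusted over the list alone. Its camera adjusted p = 0.0324 became 0.11 without WT replicate 1, 0.091 without double KO replicate 3 and adjusted p = 0.46 with an estimated correlation.

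Several markers of other cell types moved with the double KO. Erythroid cells had 4 of 13 lower and 0 higher (9 and 0 adjusted over the list alone), among them the embryonic globin gene Hba-x (-1.75 ± 0.41, adjusted p = 0.0078), with a list median of -0.898. The list's camera adjusted p = 0.00215 became 0.0595 without WT replicate 1, 0.11 by fry and adjusted p = 0.649 with an estimated correlation. Platelet, macrophage and other blood cells had 2 lower, with the platelet chemokine gene Pf4 at -3.55 ± 0.88 (adjusted p = 0.0112), and 1 higher of 18 (list adjusted p = 0.991). Foregut and visceral endoderm had 9 of 27 higher and 0 lower (11 and 0 adjusted over the list alone, median 0.341, camera adjusted p = 0.000375, adjusted p = 0.275 with an estimated correlation). The gut hormone gene Pyy was among them (0.71 ± 0.13). Endocardium and endothelium split into 4 higher and 7 lower of 28, the same adjusted over the list alone (0.927). There, the natriuretic peptide receptor gene Npr3 (-1.24 ± 0.19) and the angiopoietin receptor gene Tek (-1.19 ± 0.23) were lower and the VEGF receptor gene Flt1 (1.09 ± 0.22) was higher. Proepicardium and epicardium had 4 of 14 lower and 0 higher, the same adjusted over the list alone, among them Tbx18 (-0.94 ± 0.20) and Wt1 (-0.90 ± 0.19), transcription factors of the epicardium. Its camera adjusted p = 0.036 rose to between 0.0593 and 0.172 with array weights, with centred arrays or without the dimmest probe sets. It was 0.312 without WT replicate 2, 0.0762 without double KO replicate 1, 0.0607 without double KO replicate 2, 0.116 by fry and adjusted p = 0.649 with an estimated correlation.

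Neural tissue had 2 higher, with Pax6 at 1.84 ± 0.16, and 1 lower of 19 (5 and 2 adjusted over the list alone, list adjusted p = 0.363, and 0.0167 by fry). Pharyngeal mesenchyme and neural crest had 1 higher and 2 lower of 19 (0.621), extracellular matrix and cushion 3 and 3 of 29 (0.834) and smooth muscle 0 and 2 of 12 (0.442). No member was called among anterior Hox genes (0 of 14, 0.927), BMP response (0 of 11, 0.991), Wnt response (0 of 8, 0.834) or Notch response (0 of 6, 0.834). Of 9 widely used reference genes, 3 fell, among them Hprt (-0.68 ± 0.10), which is X-linked, and Ppia (-0.42 ± 0.08), and 0 rose (4 and 2 adjusted over the list alone, list adjusted p = 0.146, and 0.00267 by fry). Sex-linked genes had 3 higher and 1 lower of 4 (0.133, and between 0.00107 and 0.0252 by fry, with centred arrays or without WT replicate 3), with Eif2s3y at 4.74 ± 0.36 and Xist at -4.29 ± 0.35. In targeted genes, 1 of 2 was called here and in Nkx2-5 KO and 0 in Tbx5 KO (list adjusted p = 0.927, 0.594 and 0.335). Adjusted over the list alone, 2 were called in double KO, 1 in Nkx2-5 KO and 1 in Tbx5 KO.

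Double KO hearts differed from WT in 4672 genes (23.4%), 1804 higher and 2868 lower. Among the 810 genes that changed by at least 1 log2 unit, 169 were higher and 641 lower. The median change over all genes was 0.064, and -0.06 with centred arrays, which gave 779 genes higher and 3769 lower. Of the 2868 lower genes, 115 were also called lower in both single KOs, 367 in Nkx2-5 KO alone, 114 in Tbx5 KO alone and 2272 in neither, where genes called higher in a single KO count as not lower. Of the 1804 higher genes, 1476 were called higher in neither single KO. A gene not called in a single KO may still have changed there. When the double KO also had to differ from each single KO, 84 genes were higher and 647 lower.

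**Figure D3:**
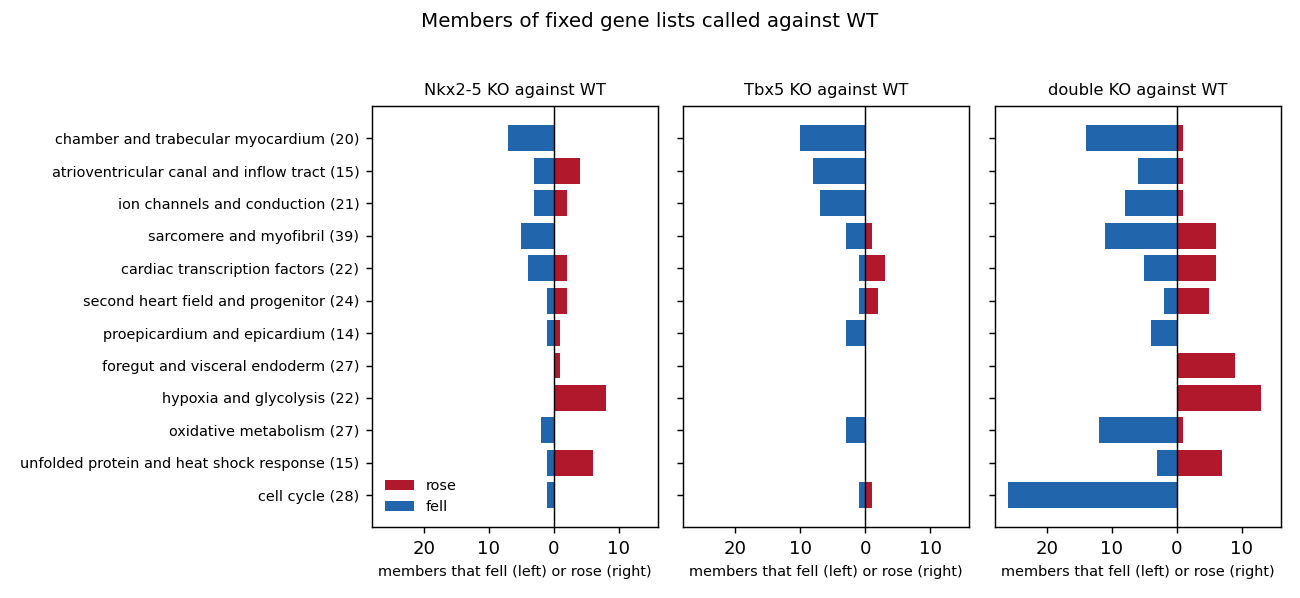
The x axis counts the members of 12 gene lists, named on the y axis with their numbers of measured genes, that rose (right of 0) or fell (left of 0) at adjusted p under 0.05 in each KO group against WT. In double KO, 26 of 28 cell cycle genes fell, against 1 in Nkx2-5 KO and 1 in Tbx5 KO. The list medians were -1.07, -0.254 and -0.125. Adjustment was made within each comparison, so the counts are not on a common scale. The smallest absolute log2 change called was 0.231 in double KO, 0.312 in Nkx2-5 KO and 0.369 in Tbx5 KO.

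The direct comparison of the single KOs asked where these groups differ from each other. They differ in both genotype labels and also in the pattern of Xist and Y-linked genes. A difference between them can therefore not be assigned to the losses alone. Vsnl1 differed most, at -5.47 ± 0.19 in Tbx5 KO against Nkx2-5 KO (adjusted p = 1.3e-08), followed among cardiac genes by Cacna2d2 (-3.65 ± 0.15). In all, 19 genes moved in opposite directions from WT, 11 of them higher in Nkx2-5 KO and lower in Tbx5 KO. These 11 included Vsnl1, Cacna2d2, Hcn4, the signalling regulator gene Rgs6 (-3.06 ± 0.16) and Sphkap (-1.69 ± 0.13), the last 2 picked after their values were seen. The other 8 included Hand1 (1.71 ± 0.13), Myocd (1.04 ± 0.10) and Ddc (3.22 ± 0.25), which encodes an enzyme of dopamine and serotonin synthesis. Ddc was also picked after its values were seen. In the same comparison Xist was higher by 5.01 ± 0.35, Prl8a2 by 3.37 ± 0.27, Erv3 by 3.33 ± 0.19 and the imprinted Plagl1 by 3.54 ± 0.51, while Eif2s3y (-5.20 ± 0.36) and Uty (-3.88 ± 0.28) were lower. There were 476 genes in all, 202 higher and 274 lower in Tbx5 KO, with 254 without Nkx2-5 KO replicate 1, 282 without Tbx5 KO replicate 1 and 1424 with array weights.

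Most genes called in double KO against Nkx2-5 KO were lower. Vsnl1 fell by 4.99 ± 0.19 (adjusted p = 4.07e-08). Cacna2d2 (-3.83 ± 0.15), Bmp10 (-3.52 ± 0.21) and Nppa (-2.59 ± 0.26) fell too. Plagl1 rose by 2.87 ± 0.51, Tdgf1, a coreceptor of Nodal signalling, by 2.15 ± 0.31 and the chemokine gene Cxcl12 by 2.12 ± 0.29. The comparison called 1109 genes, 202 higher and 907 lower. That total was 524 without Nkx2-5 KO replicate 1, 558 without Nkx2-5 KO replicate 2, 521 without double KO replicate 2, 570 with only the arrays compared and 2481 with array weights. With centred arrays 117 genes were higher and 1161 lower, and after quantile normalization again 254 and 682.

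Double KO against Tbx5 KO, groups that differ in the Nkx2-5 label and also in the pattern of Xist and Y-linked genes, called 2139 genes. Of these 572 were higher and 1567 lower, against 302 and 1917 with centred arrays. The falls were led by Prl3d3 (-4.50 ± 0.35), Xist (-4.38 ± 0.35), Erv3 (-3.48 ± 0.19) and Tlcd4 (-3.35 ± 0.47), and the rises by Eif2s3y (5.15 ± 0.36), Uty (3.68 ± 0.28) and the imprinted receptor gene Igf2r (2.78 ± 0.47, adjusted p = 0.00259). Of these 4 falls and the 4 largest rises, 7 genes were sex-linked, imprinted or of the trophoblast and decidua list, counting Grb10, an imprinted growth inhibitor (3.05 ± 0.83, adjusted p = 0.0345). The Grb10 call ended without any 1 of the 3 Tbx5 KO arrays or without double KO replicate 1 or 2 (0.0685 to 0.113). The total was 1371 without Tbx5 KO replicate 1 and 1300 without double KO replicate 2.

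**Figure D4:**
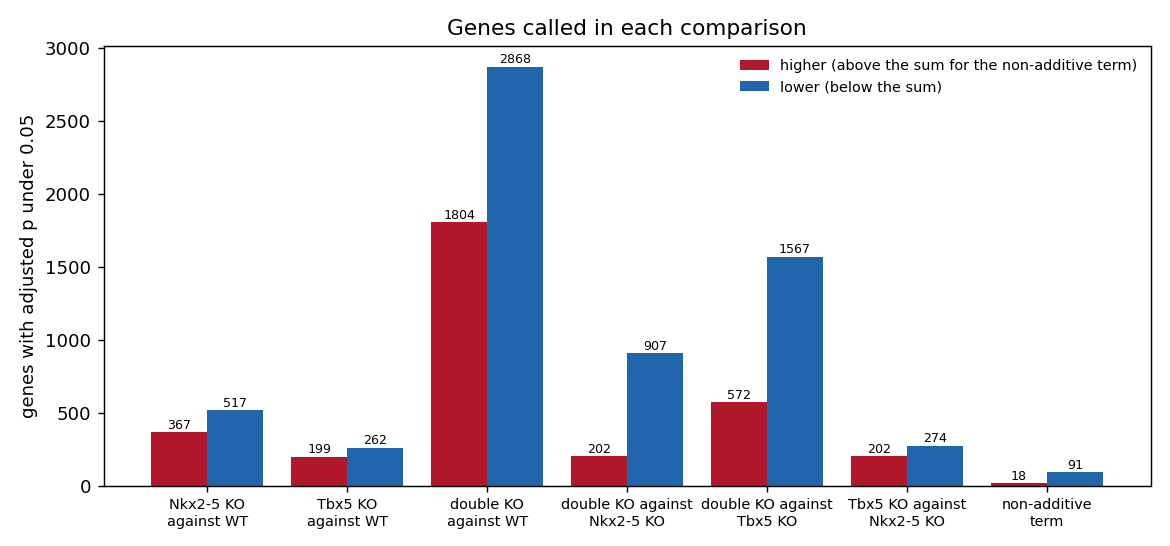
Bars give the numbers of genes called at adjusted p under 0.05 on the y axis for each of the 7 comparisons on the x axis, higher and lower apart, from a baseline of 0. Against WT the double KO had 4672 genes, Nkx2-5 KO 884 and Tbx5 KO 461. The adjusted threshold reaches smaller changes where more genes differ. At an unadjusted p under 0.05 from the limma fit, the numbers were 7285, 3538 and 2978.

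Calls overlapped between the comparisons with WT. Nkx2-5 KO and Tbx5 KO shared 44 higher and 117 lower genes, where independent calls would share 3.66 and 6.79. Among those lower in both were Nppa, Nppb, Pln, Kcna5, Casq2, Hopx and Myoz2. Nkx2-5 KO and double KO shared 269 higher and 482 lower genes (33.2 and 74.4 if independent), and Tbx5 KO and double KO 102 and 229 (18 and 37.7). Simulated groups without any change shared 0 genes in 100 simulations, where few genes can be called at all. They do not gauge what the same 3 WT arrays, used in each comparison, add among called genes. Across genes, the Pearson correlation of log2 changes was 0.49 for the single KOs against 0.5 in the simulations, 0.75 for Nkx2-5 KO and double KO and 0.61 for Tbx5 KO and double KO. The covariance of the single KO changes was 0.0358, against 0.0109 simulated. The WT arrays were too few to be divided between comparisons, so part of each overlap may rest on them. Without single arrays, the overlap of the single KOs ranged from 50 to 101 when any of WT replicates 1 and 3, Nkx2-5 KO replicates 1 and 3 or the 3 Tbx5 KO arrays was left out, against 161 with all. That of Nkx2-5 KO with double KO fell from 751 to between 147 and 290 without WT replicate 1 or 3 or Nkx2-5 KO replicate 1 or 3. For Tbx5 KO with double KO it fell from 331 to between 146 and 200 without WT replicate 1 or 3 or any Tbx5 KO array, while array weights gave 422, 1648 and 683.

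Some genes in the double KO departed from the sum of both single changes. Nppb lay 2.52 ± 0.37 above the sum (adjusted p = 0.00923), with levels of 12.80 ± 0.32 in WT, 10.01 ± 0.11 in Nkx2-5 KO, 9.62 ± 0.56 in Tbx5 KO and 9.34 ± 0.39 in double KO, so that either single loss took it most of the way down. Kcna5 (2.21 ± 0.27), Shox2, a transcription factor of the sinus node (1.52 ± 0.21), and Nr2f1 (1.52 ± 0.23) were also above. Nppa, at 0.72 ± 0.37 (adjusted p = 0.618), was not called. Alcam, an adhesion molecule of early heart cells, lay -2.04 ± 0.24 from the sum (adjusted p = 0.00421), with 12.07 ± 0.05 in WT, 10.96 ± 0.16 in Nkx2-5 KO, 12.36 ± 0.19 in Tbx5 KO and 9.21 ± 0.39 in double KO. Birc5 (-1.47 ± 0.18, adjusted p = 0.00506), Wnt2 (-2.22 ± 0.27), Wnt5a (-1.31 ± 0.18) and Lef1 (-1.40 ± 0.19) were below the sum as well. So were Prl3d3 (-5.62 ± 0.49) and Erv3 (-3.69 ± 0.27), and 9 of the 29 measured trophoblast and decidua genes were called here. That list, made after such genes had been seen to be high in Tbx5 KO, had a median of -0.45. Its camera adjusted p = 2.67e-13 was adjusted p = 0.000649 with an estimated correlation.

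The cell cycle list was below the sum, with 2 of 28 genes called and 18 adjusted over the list alone, 0 above in either (median -0.669, camera adjusted p = 7.72e-18, adjusted p = 0.47 with an estimated correlation, 0.179 by fry). Hypoxia and glycolysis had 0 of 22 called and a median of -0.265 (camera adjusted p = 5.8e-05, adjusted p = 0.955 with an estimated correlation, 0.699 by fry). Cardiac transcription factors (0 of 22, adjusted p = 0.0218) and proepicardium and epicardium (1 of 14 above, Mab21l2 at 1.50 ± 0.24, adjusted p = 0.026) lost their calls with an estimated correlation (adjusted p = 0.47 and 0.955) and by fry (0.179 and 0.699). The former call ended without WT replicate 3, Nkx2-5 KO replicate 1, Tbx5 KO replicate 3 or double KO replicate 1 (0.063 to 0.109), and the latter without WT replicate 2, Nkx2-5 KO replicate 3, Tbx5 KO replicate 2 or 3 or double KO replicate 3 (0.0515 to 0.437). After quantile normalization again both were lost (0.105 and 0.0911), the former also without the dimmest probe sets (0.0903) and the latter with array weights (0.183). No other fixed list was called, the lowest adjusted p being 0.0586 for anterior Hox genes and for the unfolded protein and heat shock response. Anterior Hox genes lay higher at 0.00128 without WT replicate 1 and between 0.0151 and 0.0329 with array weights or without Nkx2-5 KO replicate 2 or 3 or Tbx5 KO replicate 2. The unfolded protein list lay lower at 0.0153 to 0.038 with array weights or without WT replicate 2, Tbx5 KO replicate 2 or double KO replicate 1.

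The non-additive term was called for 109 genes, 18 above the sum and 91 below, and 45 of the 91 were called in neither single KO. The total was 48 to 68 without WT replicate 1 or 3, Nkx2-5 KO replicate 1, any Tbx5 KO array or double KO replicate 1 or 2, and 264 without double KO replicate 3. It was 343 with array weights and 61 with a replicate block. At least 109 genes were called in 5 of 100 splits of the arrays, the real one included. The highest others kept some real groups whole, so these splits cannot decide on chance. Changes beyond both single KOs, in the same direction against WT and each single KO, were found for 731 genes. Of these, 84 were higher and 647 lower (141 and 483 after quantile normalization again, 42 and 828 with centred arrays). The total of 731 became 385 without Nkx2-5 KO replicate 1, 355 without Nkx2-5 KO replicate 2, 335 without double KO replicate 2 and 1265 with array weights.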

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

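The tests on sex-linked, imprinted, trophoblast and decidua genes were chosen only after the results had been seen, and the splits of the arrays were chosen before.

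Xist and the Y-linked genes Eif2s3y and Uty differed along the Nkx2-5 label, which was seen as a difference between groups. The tables argue against a change of Xist level with no difference in sex, since the mean of Eif2s3y and Uty was 3.08 log2 units higher in the lowest array with the Nkx2-5 KO than in the highest without. Of the genes called in Nkx2-5 KO against WT, 95.2% were neither X- nor Y-linked. Only 748 of all genes tested (3.75%) were X- or Y-linked, fewer than the 884 calls. They could not have made up all calls, so this share decides nothing on the sex difference. In both measures, 12 of 12 arrays lay on the side of their Nkx2-5 label. This is the pattern of mainly male tissue in the Nkx2-5 KO and double KO arrays and mainly female tissue in the others. The count was set up after the pattern had been seen, so it restates it. Whether autosomal genes that differ between the sexes account for part of the calls cannot be told apart from the loss of Nkx2-5 in Nkx2-5 KO or double KO against WT, in double KO against Tbx5 KO or in Tbx5 KO against Nkx2-5 KO, because 0 arrays had the other sex pattern than the rest of their genotype class.

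Igf2r, Grb10, Zim1 and Igf2, which are imprinted, spanned 2.54 to 4.36 log2 units over the 3 WT arrays, with WT replicate 3 at the level of the Nkx2-5 KO arrays. Cdkn1c, a maternally expressed gene, varied in another way, from 9.37 to 12.7 in WT with a mean of 11.6, nearer the highest value. The smallest range of the 4 genes, 2.54, lies within 1 genotype label, but it restates the spread they were picked for and is no separate test. The tables argue against WT replicate 3 differing in general. There 31 genes lay over 1 log2 unit from both other WT arrays, against 42 for replicate 1 and 41 for replicate 2. Along the Nkx2-5 label, 16 paternally expressed genes had a median change of -0.388 (percentile 0 of random lists) and 15 maternally expressed genes one of 0.126 (percentile 98.39), but both lists were made after such genes had been seen to differ, so this does not support fewer maternal imprints in the arrays without the Nkx2-5 KO, which stay open. The list tests of Nkx2-5 KO against WT were lost with an estimated correlation (adjusted p = 0.505 for both lists), and Igf2, which is paternally expressed and in neither list, was not called (2.39 ± 0.87, adjusted p = 0.151). WT replicate 3 was the 1 array without the Nkx2-5 KO at or above the lowest of the 6 others for all of Igf2r, Grb10 and Zim1. Its Xist level was that of the arrays without the Nkx2-5 KO. In this 1 array, high values of these genes went with neither the Nkx2-5 KO nor the male pattern. Elsewhere, loss of Nkx2-5 cannot be told apart from sex, which follows the same label, or from origin, which is untested.

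Genes of trophoblast and decidua were higher in Tbx5 KO, where 13 of 29 measured members rose by 0.622 to 4.32 log2 units. The tables argue against loss of Tbx5 raising these genes whatever the Nkx2-5 state, since 0 of the 13 also rose in double KO against Nkx2-5 KO, where their changes ran from -1.30 to 0.35. Carried-over extra-embryonic tissue cannot be told apart from an effect of Tbx5 loss that needs Nkx2-5, since the list median of 0.325, at percentile 100 of random lists, comes from a list made after these genes had been seen to be high and restates that. Of the 29, 3 lay above the median of all genes in WT hearts, 0 were in a fixed list and 1 was in another list made later. The dissection of the hearts described in the labels would remove such tissue if complete.

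The difference that goes with the Tbx5 label differed between the Nkx2-5 labels for 109 genes by the test of the non-additive term. Among those named, the term was positive for Nppb (2.52), Kcna5 (2.21), Shox2 (1.52), Nr2f1 (1.52), Tspan8 (1.50), Mab21l2 (1.50), Casq2 (1.26) and Ccn2 (1.24). It was negative for Prl3d3 (-5.62), Erv3 (-3.69), Prl8a2 (-2.87), Prl2c5 (-2.82), S100a6 (-2.35), Wnt2 (-2.22), Alcam (-2.04), Prl7a1 (-1.96), Birc5 (-1.47), Cacna1d (-1.44), Lef1 (-1.40), Wnt5a (-1.31), Cacna2d2 (-1.14) and Aurkb (-1.05). The calls of Casq2, Ccn2, S100a6, Cacna1d, Cacna2d2 and Aurkb ended without 1 array, with highest adjusted p values of 0.0991 without Nkx2-5 KO replicate 1, 0.0606 without Nkx2-5 KO replicate 1, 0.084 without double KO replicate 2, 0.0626 without Nkx2-5 KO replicate 1, 0.11 without Nkx2-5 KO replicate 1 or Tbx5 KO replicate 3 and 0.115 without Tbx5 KO replicate 1, and other arrays ended them too.

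In data that the comparisons did not use, the 13768 probe sets with several or no gene symbols, 3 were called in Nkx2-5 KO against WT, 10 in Tbx5 KO against WT and 1149 in double KO against WT, of which 640 were higher and 509 lower.

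For each pairwise comparison, the 10 splits of the 6 arrays are too few to give a share under 0.05. The real split was the 1 with the most genes in each, with 884 in Nkx2-5 KO against WT (highest other 0), 461 in Tbx5 KO against WT (1), 4672 in double KO against WT (0), 1109 in double KO against Nkx2-5 KO (0), 2139 in double KO against Tbx5 KO (1) and 476 in Tbx5 KO against Nkx2-5 KO (0). For the non-additive term, 5 of 100 splits of the 12 arrays, the real one included, gave at least 109 genes. The highest others were 2139 and 495, in splits that kept 2 of the real groups whole. Such splits can carry differences between the real groups into the term. They therefore cannot decide on chance, which is not excluded. For changes beyond both single KOs, 1 of 100 splits, the real one, gave 731 genes and the highest other 407. These splits mix all 4 groups, so they ask only whether the groups differ at all. They cannot exclude chance for changes beyond the single KOs.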

How the results depend on the processing

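The counts without X- and Y-linked genes and without imprinted, trophoblast and decidua genes were chosen after seeing the data, and the other alternatives before. Without X- and Y-linked genes the counts against WT were 841 for Nkx2-5 KO, 420 for Tbx5 KO and 4504 for double KO. Without the imprinted, trophoblast and decidua genes they were 893, 438 and 4673. Of the counts of genes, 106 stayed within 1.5 times under alternatives other than leaving out a replicate and 29 did not. With array weights there were 2132 genes in Nkx2-5 KO against WT, 933 in Tbx5 KO against WT, 2481 in double KO against Nkx2-5 KO, 1424 in Tbx5 KO against Nkx2-5 KO, 343 non-additive and 1265 beyond both single KOs, and overlaps of 422 (single KOs), 1648 (Nkx2-5 KO and double KO) and 683 (Tbx5 KO and double KO). The weights ran from 0.545 for double KO replicate 3 to 2.64 for Nkx2-5 KO replicate 1, and the cause of the higher counts was not tested further. Only the arrays compared gave 570 genes in double KO against Nkx2-5 KO, with fewer arrays to estimate the spread. At adjusted p under 0.01, a stricter threshold by construction, the 6 pairwise counts were 172, 137, 2587, 362, 1001 and 227 in the order of the splits above, with 33 non-additive, 236 beyond both, and overlaps of 25, 142 and 91. With at least 1 log2 unit they were 142, 117, 810, 184, 376 and 171, with 98 beyond both.

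A replicate block gave 645, 378, 4186, 873, 1869 and 417 genes in the same order, 600 beyond both and overlaps of 119, 544 and 266, all within 1.5 times, and 61 non-additive, a drop whose cause was not tested. The numbers do not pair the arrays: deviations from the group mean correlated between -0.27 and 0.21 for the 18 same-number pairs, and 0 of 12 arrays matched its own number best in every other group. Leaving out each replicate in turn, with fewer arrays in the fit, gave 169 to 903 genes in Nkx2-5 KO against WT, 212 to 465 in Tbx5 KO against WT, 3254 to 4610 in double KO against WT, 521 to 1255 in double KO against Nkx2-5 KO, 1300 to 2207 in double KO against Tbx5 KO, 254 to 428 in Tbx5 KO against Nkx2-5 KO, 48 to 264 non-additive, 335 to 906 beyond both, and overlaps of 50 to 218, 147 to 896 and 146 to 389. One list turned, erythroid cells in the non-additive term without WT replicate 2 (adjusted p = 0.0323, with the list higher, the highest being 0.947 without double KO replicate 2), and the cause was not tested. Values were counted as kept when they stayed on their side of the threshold, with the same direction if called. Direction was not compared where neither value was called. For named genes, 2425 values were kept under other alternatives, 64 were lost and 8 gained. When a replicate was left out these were 1604, 296 and 2. For lists the numbers were 1177, 56 and 14, and 824, 23 and 22. Of the named genes called, 29 of 58 in Nkx2-5 KO, 30 of 49 in Tbx5 KO and 73 of 95 in double KO against WT were called without any 1 array. Background signal was not measured here, so the dimmest genes have no known floor.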

Other observations

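The tests in this part were chosen only after the results had been seen. Some immediate early genes, which answer stimulation and stress within minutes, rose in hearts that lacked Nkx2-5. The same hearts had the male pattern of Xist and Y-linked genes, so the rise cannot be assigned to the loss of Nkx2-5. The list was added after the data had been seen, so its tests are no separate support. Of 22 measured genes, 13 rose and 1 fell in double KO against WT (median 0.749, camera adjusted p = 3.7e-05, adjusted p = 0.392 with an estimated correlation), and 4 rose and 1 fell in Nkx2-5 KO (median 0.518, camera adjusted p = 8.73e-09, adjusted p = 0.172 with an estimated correlation). In Tbx5 KO 0 rose and 1 fell (adjusted p = 0.569). Egr1, a transcription factor, was 1.87 ± 0.26 in double KO (adjusted p = 0.000319) and -0.03 ± 0.26 in Tbx5 KO, and Jun was 1.07 ± 0.12 and -0.08 ± 0.12. The proliferation gene Myc, a member of the list that went the other way, was -1.37 ± 0.13 in double KO (adjusted p = 2.41e-05) and -1.08 ± 0.13 in Tbx5 KO. In WT, 17 of the 22 lay above the median of all genes, and 2 were also in a fixed list.

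Replication-dependent histone genes split in double KO hearts. Of 26 measured, 5 rose and 5 fell (median -0.225, camera adjusted p = 0.372), with H3c15 at 2.53 ± 0.48 (adjusted p = 0.0024), and in either single KO 0 were called. In the non-additive term their median was -0.238 (camera adjusted p = 0.0167, adjusted p = 0.562 with an estimated correlation), with 0 called.

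Neighbours of the targeted genes were looked at because a passenger region of another strain can come along with a targeted gene. Of 20 measured genes next to Nkx2-5, 2 were called in Nkx2-5 KO, 1 in Tbx5 KO and 10 in double KO against WT. For Tbx5 these numbers were 2, 2 and 4. Of all genes tested, 4.43%, 2.31% and 23.4% were called in these comparisons. Crebrf, 2 measured genes from Nkx2-5, was 1.97 ± 0.35 in Nkx2-5 KO, 0.90 ± 0.35 in Tbx5 KO (adjusted p = 0.242) and 2.39 ± 0.35 in double KO. The call in Nkx2-5 KO (adjusted p = 0.0112) ended without WT replicate 1 (0.0506) or Nkx2-5 KO replicate 1 (0.0613). Tbx3, 1 measured gene from Tbx5, was 0.93 ± 0.16 in Nkx2-5 KO (adjusted p = 0.00876, and 0.0516 without Nkx2-5 KO replicate 1) and -0.48 ± 0.16 in Tbx5 KO. Prm1 rose from 8.62 ± 0.44 in WT to 11.12 ± 0.45 in Nkx2-5 KO and 11.12 ± 0.36 in double KO, while of the related sperm genes Prm3 rose in double KO (0.63 ± 0.12, adjusted p = 0.00229) and not in Nkx2-5 KO (0.24 ± 0.12, adjusted p = 0.339). Prm2 (0.08 ± 0.11) and Tnp2 (-0.08 ± 0.13) were not called in double KO.

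X- and Y-linked genes made up 748 of the 19938 genes tested (3.75%). They were 42 of the genes called in Nkx2-5 KO against WT (4.75%, two-sided Fisher's exact p = 0.123), 33 in Tbx5 KO against WT (7.16%, exact p = 0.000423) and 177 in double KO against WT (3.79%, exact p = 0.895). Double KO had 5.05% against Nkx2-5 KO (exact p = 0.0226) and 4.63% against Tbx5 KO (exact p = 0.0259). Tbx5 KO against Nkx2-5 KO had 6.3% (exact p = 0.00663) and the non-additive term 7.34% (exact p = 0.0679). WT and Tbx5 KO arrays had the same pattern of Xist, Eif2s3y and Uty. Genes on a chromosome are not independent of each other, and 7 such comparisons were made.

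The imprinted lists gave the following against WT. Maternally expressed genes had 1 higher and 0 lower of 15 in Nkx2-5 KO (camera adjusted p = 0.0167, adjusted p = 0.505 with an estimated correlation), 1 and 0 in Tbx5 KO (0.958) and 3 and 0 in double KO (0.0442, adjusted p = 0.505 with an estimated correlation). Paternally expressed genes had 0 higher and 2 lower of 16 in Nkx2-5 KO (0.0068, adjusted p = 0.505 with an estimated correlation), 1 and 0 in Tbx5 KO (0.776) and 0 and 4 in double KO (0.036, adjusted p = 0.57 with an estimated correlation). Of the measured genes, 10 of 15 and 12 of 16 lay above the median of all genes in WT.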
